A study of Homo sapiens with 7 samples.

How the data were processed

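Human colonic cells enriched for epithelium were profiled in 7 libraries, 3 from untreated Crohn's disease (CD) and 4 from people without inflammatory bowel disease (nIBD), each treated as 1 sample. Per the labels the libraries are 10x Genomics Chromium 3' libraries of v3 chemistry. The authors deposited 1 matrix of raw UMI counts per sample, and its header states Cell Ranger 3.1.0, while the submitters' notes state the hg38 genome. The values were tested on the files, and all were whole numbers over 36601 genes. The annotation release, the rule that selected the barcodes, and any removal of free RNA are not given in the sources used here. Gene positions come from GENCODE release 29, in which 94.6% of the genes' identifiers were found, and class or list membership used gene symbols as deposited. The labels of 1 library conflict with each other, and its group was taken from the sample title, with the other reading as an alternative.

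Sequencing depth per sample was 142673502 to 190652345 UMIs over 10455 to 15342 barcodes, and the median UMI count of a kept cell was 11190 ± 3385 (mean ± SD over samples) in CD and 15595 ± 2757 in nIBD. Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 50% mitochondrial UMIs, which left 42793 cells. The mitochondrial limit was set high because dissociated colonic epithelium carries much mitochondrial RNA. Doublets were scored against 2 simulated doublets per cell in each library, in the manner of Scrublet, and the highest-scoring cells were removed at 0.8% per 1000 cells, between 3.86% and 5.84% of a library and 2142 cells in all. The remaining 40651 cells were scaled to library size and log-transformed. Their 2000 most variable genes and 30 principal components were integrated over samples with a script that follows Harmony (theta 2, lambda 1, 10 iterations). A graph of 20 neighbours was then clustered by Leiden at resolution 1.0, with random seed 1, into 29 clusters. No free RNA was subtracted.

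Clusters were named from marker sets written before the data were examined, as were the gene lists, the comparisons, the tests and the alternatives unless stated otherwise. A cluster took the class with the highest score when at least 3 markers were detected in 10% of its cells, the score (mean log2 fold of the markers over all other cells) was at least 0.5 and a marker was among its 10 leading genes or the score was at least 1, and otherwise it stayed unnamed. Clusters also stayed unnamed with fewer than 30 cells, with more markers of another class than of their own among those 10 genes, or where another class, cycling apart, scored at least 3 and at least 0.5 of the best score. A cycling cluster of 974 cells held 4 cycling and 4 goblet markers there and kept its name. The sets were written from general knowledge of the colon, for stem or progenitor, cycling, early colonocyte, crypt-top colonocyte, BEST4+, goblet, enteroendocrine, tuft, Paneth-like, T or NK, B, plasma, myeloid, mast, fibroblast, endothelial, glial and red cells. Early and crypt-top colonocytes together made the absorptive class (13276 cells, 1451 to 2284 per sample). Stem or progenitor and cycling cells made the undifferentiated class (7556 cells, 664 to 1415 per sample). Goblet cells numbered 4101 (299 to 988 per sample), BEST4+ cells 845 (54 to 200 per sample), all epithelial cells 35422 and T or NK cells 3387 (148 to 750 per sample). Tuft cells could not be tested because no cluster was named so, and enteroendocrine genes could not because every CD sample held fewer than 30 such cells (at most 23).

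Shares of 11 classes were compared as logits, with 0.5 cell added, by a two-sided exact permutation test over all 35 splits of the 7 samples, whose smallest p is 0.0286. Adjustment was by Benjamini and Hochberg. Raw counts were summed per sample and class and compared with edgeR 4.0.16 (TMM scaling, its filter on low counts, quasi-likelihood test) at an adjusted p of 0.05, with DESeq2 1.42.0 as the second tool. Levels are TMM-scaled CPM (counts scaled to a common library size), as mean ± SD over samples. A difference of disease effect between classes was tested as an interaction with the sample as a block. Genes mostly set by the sex chromosomes or a person's own genotype (133 genes) were left out of every test, but HLA-DRB1 stayed in.

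The gene lists, written from general knowledge, covered MHC class II, MHC class I and peptide loading, interferon gamma response, type I interferon response, antimicrobial and oxidative defence, NF-kB targets and chemokines, mitochondrial-encoded genes, nuclear oxidative phosphorylation, fatty acid oxidation with ketogenesis and PPAR targets, and butyrate handling. They also covered ion and water transport, mucus and goblet products, unfolded protein response and secretion, dissociation and immediate early genes, cholesterol synthesis, hypoxia and glycolysis, cell cycle, stem cell and Wnt targets, ileal genes, distal colon genes, and tight junctions. The others were CD susceptibility genes, metallothioneins and metal handling, xenobiotic targets, cytosolic ribosomal proteins, and genes of plasma cells, of T and NK cells, of myeloid cells and of stromal and endothelial cells. A list entered a test with at least 3 measured members. It was compared with all other genes by camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation and with fry as alternatives.

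The named genes follow a written rule: passing genes with a mean log2 CPM of at least 4 and no overlap of the groups, by fold, and, where fewer than 10 passed, the genes of smallest p until 10 were named, outside BEST4+ cells. Clone-based names and immunoglobulin or T cell receptor segments were left out there. The text also names the 4 members of smallest p in each called list, or 3 where only 3 were measured. 2 genes that the rules would name are not reported here. NPR1 lay under the CPM minimum and was named outside the rule, after its values were seen. Counting floors and intervals cover counting error only.

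Each comparison was tested on data simulated from means and spread fitted to the counts, without correlation between genes, and with known changes added. Of genes changed 4-fold, edgeR recovered 87.4%, 89.8%, 80.4%, 90.6% and 84.5% in absorptive, goblet, undifferentiated, BEST4+ and T or NK cells. Of genes changed 2-fold it recovered 24%, 43.8%, 57.1%, 49.0% and 22.3%, so such changes would often be missed. Lists moved 1.5-fold were called 3 of 3 times in each class at the preset correlation. With an estimated one it was 0, 3 and 3 in absorptive, goblet and undifferentiated cells. At the preset 1, 0 and 0 unchanged lists were called, but false calls from correlation could not show. The permutation test reached an unadjusted p below 0.05 in 39.1% of draws at a shift of 1 logit and 87.7% at 2 logits, for a spread of 0.5 logits.

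The alternatives chosen in advance were at most 25% mitochondrial UMIs (17177 cells), at least 1000 genes (35007 cells), no doublet removal, no integration, Leiden resolution 2.0, the conflicting library counted as CD, each sample left out, DESeq2, DESeq2 size factors, no filter on low counts, a tested fold of at least 2, library sizes without mitochondrial genes, an edgeR test of cell counts, and shares of all kept cells. After the results of the gene tests had been seen, 6 settings were added: the barcode minimum (the lowest UMI count of any deposited barcode, higher in 2 CD libraries) as a term, leaving out both libraries of high minimum, leaving out clusters of few UMIs for their samples, stem or progenitor cells alone, crypt-top colonocytes alone, and leaving out the cycling cluster with goblet markers. The shares of that cluster and of the unnamed cluster with T or NK and cycling markers were also compared then. The T or NK comparison was added after the comparisons were fixed and run beside them. All 35 splits were also run through the same tests.

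Computation used R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, on 1 thread.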

Results

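Cells dissociated from colon without inflammation and enriched for epithelium were profiled by droplet single-cell RNA sequencing, in 3 samples from people with untreated Crohn's disease (CD) and 4 samples from people without inflammatory bowel disease (nIBD). The files held 10455 to 15342 barcodes per sample and 94728 in all. Total UMIs per sample ran from 142673502 to 159996665 in CD and from 181364076 to 190652345 in nIBD. Class shares were compared for the make-up of the epithelium. Genes were compared for programmes inside absorptive, goblet, undifferentiated and BEST4+ cells. P-values of genes and shares measure the spread between the samples that the labels list. Those of camera rest also on the correlation taken between genes.

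The CD libraries were of lower depth and quality. Barcodes with more than 50% mitochondrial UMIs made up 60.5 ± 11% (mean ± SD) in CD and 36.7 ± 3.97% in nIBD (exact permutation p = 0.0286, two-sided, the smallest that 35 splits allow). The share of barcodes kept as cells was 36.1 ± 5.41% against 53.3 ± 3.27% (exact permutation p = 0.0286). In kept cells the median UMI count was 11190 ± 3385 in CD and 15595 ± 2757 in nIBD (exact permutation p = 0.0857), and the median mitochondrial share was 29.2 ± 2.64% and 28.2 ± 3.11% (exact permutation p = 0.571). CD replicates 2 and 3 came with a lowest barcode total of 973 and 1020 UMIs, against 500 to 552 in the other libraries. That technical split leaves 1 CD library beside all 4 nIBD libraries on one side and CD alone on the other.

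No cell class was called as changed in share between CD and nIBD. With 35 splits the smallest p is 0.0286, which adjusted over 11 classes is 0.314 for a class that moves alone, so the exact test could not call a single class. Crypt-top colonocytes made up 29.9 ± 6.65% of epithelial cells in CD and 30.6 ± 4.75% in nIBD, and cycling cells 18.8 ± 2.67% and 18.2 ± 4.28% (exact permutation p = 0.771 and 0.857, 3 CD and 4 nIBD samples). Goblet cells, the mucus makers, stood at 10.2 ± 2.35% and 12.2 ± 3.11% (exact permutation p = 0.40). Early colonocytes came nearest to a difference among epithelial classes, at 8.32 ± 0.845% in CD and 6.81 ± 0.986% in nIBD (odds ratio 1.25, exact permutation p = 0.0857, adjusted p = 0.629 over 11 classes), but without integration their logit difference reversed from 0.222 to -0.730.

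Stem or progenitor cells held 2.28 ± 1.56% of epithelial cells in CD and 3.02 ± 0.516% in nIBD (exact permutation p = 0.286). BEST4+ cells, an absorptive subset that carries ion channels, held 2.12 ± 1.25% and 2.55 ± 1.09% (exact permutation p = 0.686), and enteroendocrine cells 0.483 ± 0.115% and 0.649 ± 0.256% (exact permutation p = 0.371). Among all kept cells, B cells were 3.69 ± 1.10% in CD and 1.85 ± 3.0% in nIBD (odds ratio 5.43, exact permutation p = 0.143), where 1 nIBD library held most of the nIBD share. T or NK cells (8.27 ± 1.08% and 8.08 ± 3.65%, exact permutation p = 1), plasma cells (0.913 ± 0.636% and 0.507 ± 0.517%, p = 0.314) and myeloid cells (0.801 ± 0.209% and 0.532 ± 0.331%, p = 0.314) also overlapped. The clusters of epithelium that no marker set named held 27.9 ± 0.873% of epithelial cells in CD and 25.9 ± 1.73% in nIBD (exact permutation p = 0.200).

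**Figure D1:**
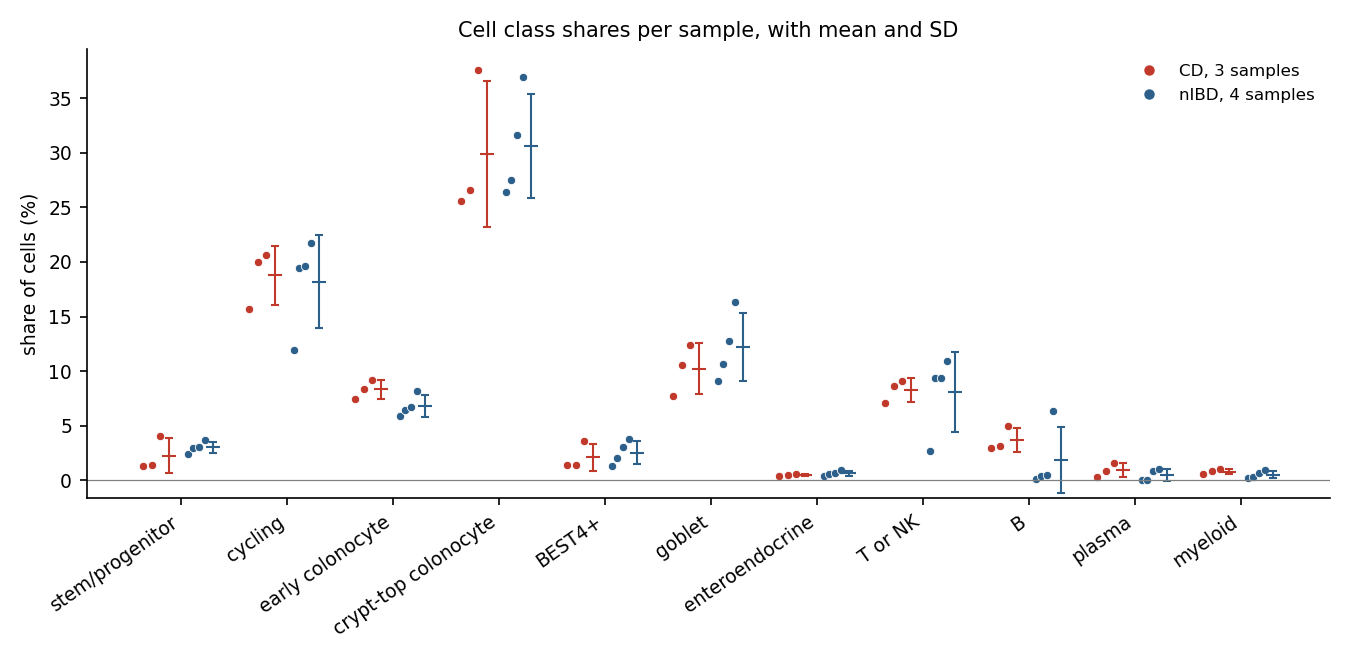
Share of each cell class in percent of cells (vertical axis, epithelial classes over epithelial cells and the last 4 over all kept cells), 1 point per sample, with the mean and SD of each group to the right of its points. The 3 CD and 4 nIBD samples overlap in every class.

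In absorptive colonocytes HLA-DRB1, a chain of the MHC class II molecule that presents antigen to CD4 T cells, rose in CD. Its level was 97.5 ± 12.3 CPM in CD and 3.83 ± 1.59 CPM in nIBD (chromosome 6, 32578769 to 32589848, log2 fold 4.67 ± 0.32, edgeR adjusted p = 0.000918, 3 CD and 4 nIBD samples). It was the only call among 13161 genes tested. Reads of this gene are shared with other DRB genes and alleles, and whether a person's genotype set its level was not tested. The call ended with at most 25% mitochondrial UMIs (log2 fold 4.04, adjusted p = 0.10) and with 1 library of conflicting labels counted as CD (4.52, adjusted p = 0.732). The lowest UMI count of any deposited barcode, the barcode minimum, was higher in 2 CD libraries than in the other 5. The fold was 4.46 without both and 4.45 with the barcode minimum as a term. The fold stayed above 4 in each of these fits, of which the last pair rest on a single CD library of low minimum. At unadjusted p below 0.05 edgeR listed 1181 genes (638 higher and 543 lower, 658 by chance), and DESeq2 called 101 genes (44 higher and 57 lower). The CD and nIBD samples did not overlap for 9.06% of genes, against 5.71% by chance.

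The genes with the next smallest p-values in absorptive colonocytes did not pass edgeR's test. HES4, a transcriptional repressor downstream of Notch, stood at 11.7 ± 1.42 CPM in CD and 3.98 ± 0.642 CPM in nIBD (chromosome 1, 998962 to 1000172, log2 fold 1.55 ± 0.19, adjusted p = 0.0897, DESeq2 adjusted p = 6.62e-08). Higher values also came from REL (0.92 ± 0.13, adjusted p = 0.174), a subunit of NF-kB, from PF4 (2.78 ± 0.42, adjusted p = 0.250), a chemokine best known from platelets, and from EPHB2 (1.16 ± 0.19, adjusted p = 0.270), a receptor of the lower crypt. DUSP2 (2.31 ± 0.39), a phosphatase of MAP kinases, and EID3 (2.25 ± 0.39), a partner of the SMC5/6 complex, had adjusted p = 0.270 and 0.280. EID3 was at 1.56 without CD replicate 1 and at 3.06 ± 0.29 with the barcode minimum as a term. Lower values came from OPN3 (-1.02 ± 0.16, adjusted p = 0.268), an opsin, from NT5E (-1.6 ± 0.27, adjusted p = 0.270), which makes adenosine from AMP, and from TRIM52-AS1 (-1.32 ± 0.21, adjusted p = 0.268), an antisense transcript whose counting strand the files do not state.

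Gene lists fixed before the data were examined were compared with limma's camera, over 84 tests of 29 lists in 3 classes. With the preset correlation 32 tests were called, 26 higher and 6 lower. With an estimated correlation none was called (3 at unadjusted p below 0.05, smallest adjusted p = 0.587), and with fry none was called (8 at unadjusted p below 0.05, smallest adjusted p = 0.412). Of the 32 calls, 16 held with each sample left out in turn, and 3 held with the barcode minimum as a term, while another was called in the opposite direction. Over all genes no list member passed in any class except HLA-DRB1 in absorptive colonocytes, so the member counts given with lists are adjusted over the list alone. Folds in brackets after a gene are log2 folds ± SE of CD over nIBD.

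**Figure D2:**
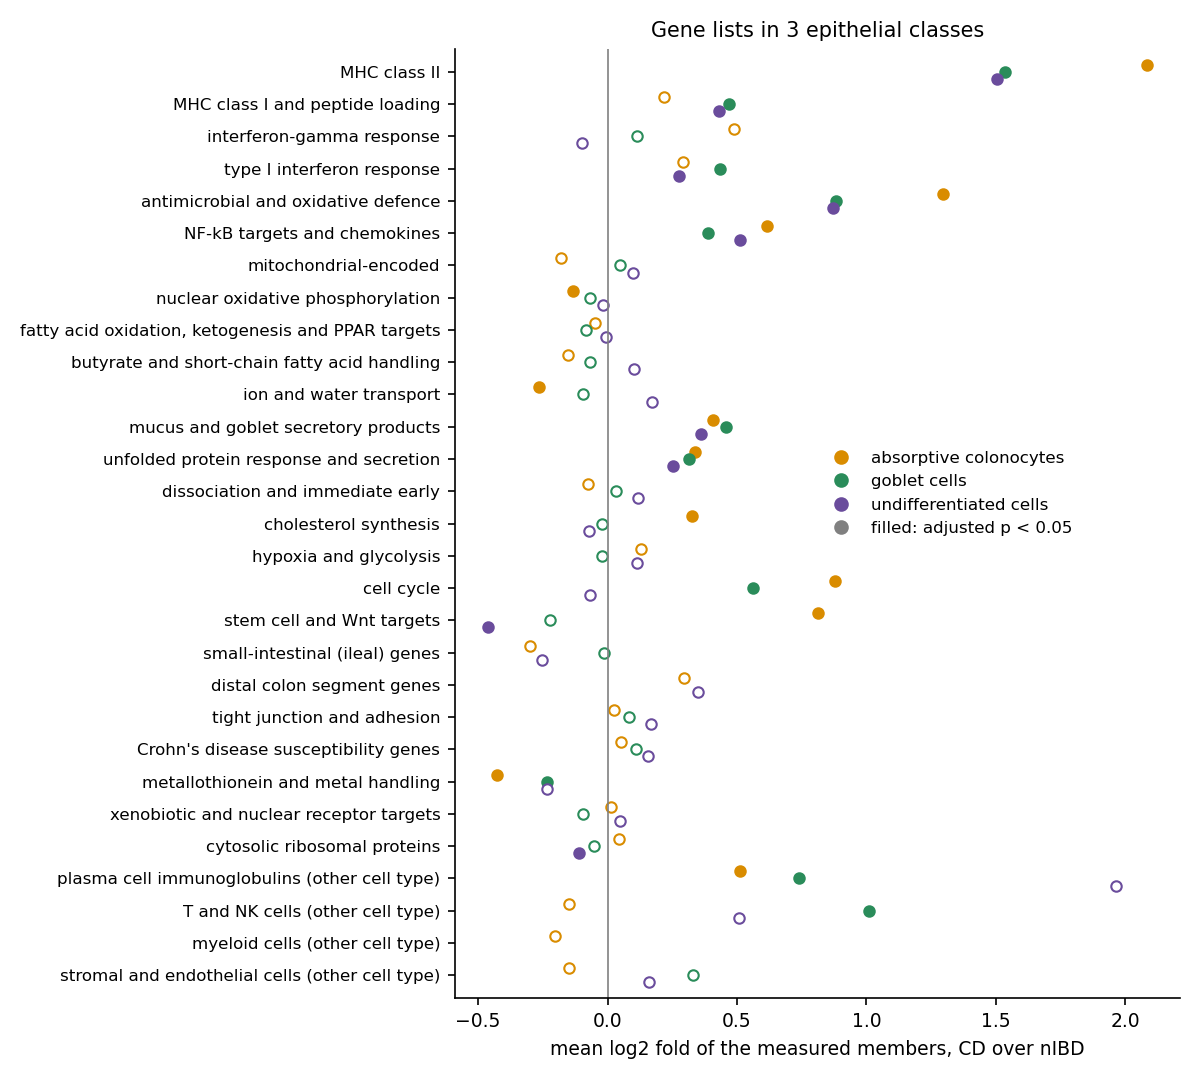
Mean log2 fold of each list's measured members, CD over nIBD (horizontal axis), for absorptive colonocytes, goblet cells and undifferentiated cells, 1 point per class. Filled points passed camera at the preset correlation, and MHC class II lies farthest to the right among them, at 2.08 in absorptive colonocytes.

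Antigen presentation and defence genes were higher as sets in CD absorptive colonocytes. All 8 measured members of the MHC class II list had positive folds (mean log2 fold 2.08, adjusted p = 2.24e-08, and adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 4 rose and 4 did not pass. HLA-DRB1 led, followed by HLA-DRA (2.88 ± 0.58), at 109 ± 58.9 CPM in CD and 14.8 ± 10.6 CPM in nIBD, by CD74 (1.80 ± 0.63), the invariant chain, and by HLA-DMA (1.56 ± 0.45), which loads peptides. CD74 moved to 2.50 without 1 nIBD library.

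Antimicrobial and oxidative defence genes had 14 positive and 3 negative folds among 17 measured (mean log2 fold 1.29, adjusted p = 0.000704, and adjusted p = 0.587 with an estimated correlation), none past the test adjusted over the list alone. LCN2, which withholds iron from bacteria, stood at 345 ± 213 CPM in CD and 72.3 ± 63.5 CPM in nIBD (chromosome 9, 128149071 to 128153455, log2 fold 2.25 ± 0.65, adjusted p = 0.40). It was at 3.05 without nIBD replicate 2. The protease inhibitor SLPI (1.34 ± 0.34, adjusted p = 0.364), the calcium-binding S100P (2.61 ± 0.82, adjusted p = 0.429) and the oxidase maturation factor DUOXA2 (2.53 ± 0.90, adjusted p = 0.478) followed. S100P came to 0.99 without CD replicate 2, DUOXA2 to 0.29 without CD replicate 3, and the list to a mean of 0.35 (adjusted p = 0.141) without CD replicate 3. The list mean reversed to -0.33, and DUOXA2 to -0.66, with the barcode minimum as a term and without both libraries of high minimum. Both fits set CD replicate 1 alone against nIBD, so they are not separate checks.

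NF-kB targets and chemokines had 14 positive folds of 18 measured (mean log2 fold 0.62, adjusted p = 0.0265, and adjusted p = 0.719 with an estimated correlation), with none past the test adjusted over the list alone. The neutrophil attractants CXCL1 (2.88 ± 0.82, adjusted p = 0.40), CXCL3 (1.52 ± 0.48) and CXCL8 (2.12 ± 0.82) were higher, and the cytokine IL32 (-0.77 ± 0.30) was lower. Without CD replicate 3 the list lost its call (adjusted p = 0.557), with CXCL1 at 1.15 and CXCL8 at 1.14. The call was also lost without nIBD replicate 1 (0.144), without nIBD replicate 3 (0.134) and with the conflicting library counted as CD (0.652). With the barcode minimum as a term, again CD replicate 1 against nIBD, the list mean reversed to -0.19. CXCL1, CXCL3 and CXCL8 reversed to -0.83, -0.37 and -2.80.

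Ion and water transport genes and nuclear oxidative phosphorylation genes were lower as sets in CD absorptive colonocytes, while the other energy lists did not pass. Of 24 measured ion and water transport genes 14 had negative folds (mean log2 fold -0.27, adjusted p = 0.0202, and adjusted p = 0.611 with an estimated correlation). Of its members 2 fell adjusted over the list alone, and 22 did not pass. SCNN1B, a subunit of the epithelial sodium channel, stood at 28.9 ± 10.6 CPM in CD and 73.4 ± 25.5 CPM in nIBD (log2 fold -1.34 ± 0.33, adjusted p = 0.364). GUCA2B, which encodes uroguanylin, stood at 351 ± 103 CPM in CD and 789 ± 302 CPM in nIBD (log2 fold -1.17 ± 0.31). The water channel AQP8 (-0.86 ± 0.32) and the carbonic anhydrase CA4 (-0.58 ± 0.23) were also lower, and GUCA2B, AQP8 and CA4 also served as markers for naming the class. This call was lost without CD replicate 1 (adjusted p = 0.164), CD replicate 2 (0.0605) or nIBD replicate 2 (0.0523), with at most 25% mitochondrial UMIs (0.266), without integration (0.367, mean -0.0594) and at Leiden resolution 2.0 (0.0993).

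Nuclear oxidative phosphorylation genes had 30 negative folds of 47 (mean log2 fold -0.14, adjusted p = 0.00630, and adjusted p = 0.720 with an estimated correlation), with none past the test adjusted over the list alone. The complex I subunits NDUFA1 (-0.87 ± 0.22), whose DESeq2 adjusted p was 0.0186, and NDUFA2 (-0.58 ± 0.18) and the complex IV subunits COX7B (-0.59 ± 0.15) and COX6C (-0.55 ± 0.16) were the examples of smallest p, with COX7B at 349 ± 24.4 CPM in CD and 524 ± 11.6 CPM in nIBD. The call was lost without CD replicate 3 (adjusted p = 0.281), with at most 25% mitochondrial UMIs (0.257), with at least 1000 genes per cell (0.256) and at Leiden resolution 2.0 (0.0823).

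Secretory genes were higher as sets in CD absorptive colonocytes, though with the barcode minimum as a term and without both libraries of high minimum only the unfolded protein response stayed so. The mucus mean was then -0.48 in both, and MUC5B and GALNT5 were at -0.0301 and -0.39 with the term. Unfolded protein response genes had 24 positive folds of 26 (mean log2 fold 0.34, adjusted p = 2.01e-05, and adjusted p = 0.587 with an estimated correlation), a call kept with every sample left out. The folding helpers SDF2L1 (0.83 ± 0.36), MANF (0.51 ± 0.18), DNAJB11 (0.47 ± 0.20) and PDIA6 (0.45 ± 0.16) led without passing the test. SDF2L1 came to 0.24 without CD replicate 1. Mucus and goblet products had 18 positive folds of 23 (mean log2 fold 0.41, adjusted p = 0.0348, and adjusted p = 0.769 with an estimated correlation). 2 members rose adjusted over the list alone, and 21 did not pass. Its leaders were the lectin ITLN1 (1.63 ± 0.43), the gel mucin MUC5B (1.45 ± 0.51), the membrane mucin MUC4 (1.16 ± 0.25) and the glycosyltransferase GALNT5 (1.01 ± 0.45). GALNT5 came to 0.12 without CD replicate 3. The mucus call was lost without CD replicate 2 (adjusted p = 0.305), CD replicate 3 (0.617) or nIBD replicate 1 (0.0878), and without the low-count filter (0.0838).

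Cholesterol synthesis genes had 17 positive folds of 20 (mean log2 fold 0.33, adjusted p = 0.00488, and adjusted p = 0.830 with an estimated correlation), none past the test adjusted over the list alone. They included the sterol carrier STARD4 (0.89 ± 0.41) and the pathway enzymes FDPS (0.68 ± 0.38) and MVD (0.67 ± 0.40). This call was lost without CD replicate 2 (adjusted p = 0.0605), CD replicate 3 (0.168) or nIBD replicate 1 (0.297). It was also lost with at most 25% mitochondrial UMIs (0.0870), and its mean reversed to -0.08 with the conflicting library counted as CD (0.199). With the barcode minimum as a term the mean was -0.19 and STARD4 was at -0.42.

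Proliferation and crypt-base genes were higher as sets in CD absorptive colonocytes, but both sets reversed with the barcode minimum as a term (means -0.33 and -0.54), as did OLFM4 (-0.98) and LEFTY1 (-0.33). Of 25 measured cell cycle genes 23 had positive folds (mean log2 fold 0.88, adjusted p = 1.81e-06, and adjusted p = 0.616 with an estimated correlation). Adjusted over the list alone, 7 rose and 18 did not pass. Examples were the nucleotide enzyme RRM2 (1.65 ± 0.47), the mitotic cyclin CCNB1 (1.61 ± 0.45), the survival factor BIRC5 (1.44 ± 0.41) and the replication factor GINS2 (1.30 ± 0.40). All 13 measured stem cell and Wnt genes were positive (mean log2 fold 0.81, adjusted p = 0.00112, and adjusted p = 0.616 with an estimated correlation). Of its members 5 rose adjusted over the list alone, and 8 did not pass. They included EPHB2, OLFM4 (2.27 ± 0.73), at 101 ± 79.5 CPM in CD and 20.9 ± 11.4 CPM in nIBD, the Nodal inhibitor LEFTY1 (1.80 ± 0.62) and the hyaluronan receptor CD44 (0.82 ± 0.28). LEFTY1 was at 1.12 without CD replicate 2. The stem cell call was lost without CD replicate 3 (adjusted p = 0.195), with at least 1000 genes per cell (0.256), without integration (0.111), at Leiden resolution 2.0 (0.508) and with at most 25% mitochondrial UMIs (0.290), where the mean was -0.0027.

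Metallothionein and metal handling genes were lower as a set in CD absorptive colonocytes, 14 of 18 with negative folds (mean log2 fold -0.43, adjusted p = 0.00421, and adjusted p = 0.587 with an estimated correlation), none past the test adjusted over the list alone. MT1X (-1.36 ± 0.47), MT1E (-0.94 ± 0.43), the zinc importer SLC39A4 (-0.51 ± 0.22) and the iron store FTH1 (-0.41 ± 0.20) led, and reads of the metallothioneins are shared between near copies. That call was lost without CD replicate 2 (adjusted p = 0.0581) and with at most 25% mitochondrial UMIs (0.0774). Plasma cell genes, which epithelium should lack, were higher as a set with no member past either test (7 of 8 positive, mean log2 fold 0.51, adjusted p = 0.0476, and adjusted p = 0.769 with an estimated correlation) with IGKC (1.73 ± 0.93), DERL3 (1.06 ± 0.45), IGHM (0.99 ± 0.50) and MZB1 (0.51 ± 0.41). Without CD replicate 2 that mean was -0.36 and IGKC was at -0.0048. The mean was 1.18 without CD replicate 3, and IGKC was at 2.76 without nIBD replicate 2. That call was lost without CD replicate 1 (adjusted p = 0.08), CD replicate 2 (0.40), nIBD replicate 1 (0.0617) or nIBD replicate 3 (0.844). It was also lost with at most 25% mitochondrial UMIs (0.458, mean -0.74), without integration (0.159, mean -0.11), without doublet removal (0.0569), with DESeq2 size factors (0.0507), without low-UMI clusters (0.0520) and with the barcode minimum as a term (0.554, mean -0.0817).

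The other lists did not pass camera in absorptive colonocytes. Immune lists were MHC class I (mean log2 fold 0.22, adjusted p = 0.0851), interferon gamma response (0.49, adjusted p = 0.373) and type I interferon response (0.29, adjusted p = 0.103). Metabolic lists were mitochondrial-encoded genes (-0.18, adjusted p = 0.145), fatty acid oxidation and PPAR targets (-0.05, adjusted p = 0.618), butyrate handling (-0.15, adjusted p = 0.470), hypoxia and glycolysis (0.13, adjusted p = 0.789) and xenobiotic targets (0.01, adjusted p = 0.935). Lists of place and structure were ileal genes (-0.30, adjusted p = 0.955), distal colon genes (0.29, adjusted p = 0.955), tight junctions (0.02, adjusted p = 0.935), CD susceptibility genes (0.05, adjusted p = 0.345), ribosomal proteins (0.04, adjusted p = 0.672) and dissociation genes (-0.07, adjusted p = 0.374). Genes of other cell types were T and NK cells (-0.15, adjusted p = 0.905), myeloid cells (-0.20, adjusted p = 0.601) and stromal cells (-0.15, adjusted p = 0.878). The test leaned against the sign of the mean for ileal, distal colon, tight junction, xenobiotic and T and NK genes. The median was -0.01 for tight junctions, -0.13 for xenobiotic targets and 0.04 for myeloid genes.

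In goblet cells no gene passed edgeR's test among 12763, although HLA-DRB1 and B3GNT6, the enzyme that builds core 3 O-glycans on mucin, each reached adjusted p = 0.0572. B3GNT6 stood at 55.1 ± 5.24 CPM in CD and 23.0 ± 3.69 CPM in nIBD (chromosome 11, 77034398 to 77041973, log2 fold 1.26 ± 0.15, DESeq2 adjusted p = 1.05e-08, 3 CD and 4 nIBD samples). HLA-DRB1 stood at 50.2 ± 14.8 CPM in CD and 3.14 ± 2.21 CPM in nIBD (log2 fold 4.06 ± 0.47). Both passed with at most 25% mitochondrial UMIs (log2 folds 4.01 and 1.57 for HLA-DRB1 and B3GNT6, each at adjusted p = 0.0017). With the barcode minimum as a term HLA-DRB1 was at 4.16, B3GNT6 at 1.41 and NFKB2 at 1.23, in a fit that rests on a single CD library of low minimum. IFITM1, an interferon-induced membrane protein, followed (chromosome 11, 313506 to 315272, log2 fold 2.67 ± 0.39, adjusted p = 0.196, DESeq2 adjusted p = 5.56e-07). At unadjusted p below 0.05 edgeR listed 1261 genes (703 higher and 558 lower, 638 by chance). DESeq2 called 96 genes (61 higher and 35 lower), and 10.8% of genes did not overlap, against 5.71% by chance.

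Higher values in CD goblet cells also came from the vesicle GTPase ARF5 (1.42 ± 0.25, adjusted p = 0.243), the ferlin FER1L6 (1.21 ± 0.21, adjusted p = 0.243), the helicase RTEL1 (1.09 ± 0.19) and the exonuclease ISG20 (0.91 ± 0.17). Lower values came from the steroid enzyme HSD17B2 (-1.0 ± 0.16, adjusted p = 0.240), the ubiquitin ligase RNF44 (-0.82 ± 0.13) and the membrane skeleton protein ADD3 (-0.75 ± 0.13).

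Antigen presentation was higher as a set in CD goblet cells in both MHC classes. All 8 measured MHC class II members were positive (mean log2 fold 1.54, adjusted p = 1.81e-06, and adjusted p = 0.587 with an estimated correlation). 5 members rose adjusted over the list alone, and 3 did not pass. HLA-DRA (2.58 ± 0.54), CD74 (1.28 ± 0.45) and HLA-DMA (0.97 ± 0.34) stood beside HLA-DRB1. All 16 MHC class I genes were positive (mean log2 fold 0.47, adjusted p = 3.52e-06, and adjusted p = 0.611 with an estimated correlation). Adjusted over the list alone, 2 rose and 14 did not pass. HLA-C, whose reads are shared between alleles and related genes, stood at 875 ± 120.3 CPM in CD and 427 ± 113 CPM in nIBD (log2 fold 1.03 ± 0.21), with HLA-E (0.61 ± 0.16), HLA-F (0.84 ± 0.39) and the immunoproteasome subunit PSMB8 (0.60 ± 0.22). Type I interferon genes were called too (16 of 20 positive, mean log2 fold 0.44, adjusted p = 0.00124, and adjusted p = 0.711 with an estimated correlation), and 2 rose adjusted over the list alone. IFITM1 and ISG20 led, with IFI27 (0.85 ± 0.29) and OASL (0.61 ± 0.24). That call was lost without CD replicate 3 (adjusted p = 0.174) or nIBD replicate 3 (0.0574), and its mean reversed to -0.31 without both libraries of high minimum.

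Defence genes were higher as a set in CD goblet cells, 12 of 16 positive (mean log2 fold 0.88, adjusted p = 0.00112, and adjusted p = 0.587 with an estimated correlation). Of its members 5 rose adjusted over the list alone, and 11 did not pass. LCN2 stood at 290.5 ± 152 CPM in CD and 69.2 ± 38.4 CPM in nIBD (log2 fold 2.08 ± 0.44, adjusted p = 0.243). DUOX2, the hydrogen peroxide source at the gut surface, had log2 fold 2.89 ± 0.61 (chromosome 15, 45092650 to 45114344) and 1.69 without CD replicate 3. SLPI (0.73 ± 0.21) and S100P (1.77 ± 0.57) followed, with S100P at 0.69 without CD replicate 2. NF-kB targets and chemokines had 14 positive folds of 16 (mean log2 fold 0.39, adjusted p = 0.00193, and adjusted p = 0.587 with an estimated correlation), none past the test adjusted over the list alone. Examples were NFKB2 (0.78 ± 0.21), the chemokines CCL20 (1.28 ± 0.37) and CCL28 (0.56 ± 0.21), and the NF-kB inhibitor TNFAIP3 (0.50 ± 0.20), with CCL20 at -0.0896 with the barcode minimum as a term.

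The mucus programme of CD goblet cells was higher as a set, with 20 of 23 members positive (mean log2 fold 0.46, adjusted p = 2.29e-06, and adjusted p = 0.587 with an estimated correlation). 3 members rose adjusted over the list alone, and 20 did not pass. ITLN1 stood at 2004 ± 302 CPM in CD and 794 ± 319.9 CPM in nIBD (chromosome 1, 160876539 to 160885170, log2 fold 1.33 ± 0.29), and MUC4 (0.52 ± 0.13) and the trefoil peptide TFF1 (1.40 ± 0.48) stood beside B3GNT6, ITLN1 being also a marker of the class. TFF1 was at 0.54 without CD replicate 3. Unfolded protein response genes had 24 positive folds of 26 (mean log2 fold 0.31, adjusted p = 1.45e-05, and adjusted p = 0.587 with an estimated correlation), none past the test adjusted over the list alone. The chaperone HSPA5 stood at 656 ± 132 CPM in CD and 409 ± 96.9 CPM in nIBD (log2 fold 0.68 ± 0.21), with SDF2L1 (0.84 ± 0.21), DDIT3 (0.70 ± 0.27) and CALR (0.36 ± 0.14). The mucus and unfolded protein calls held with each sample left out, and the latter was lost with the conflicting library counted as CD (adjusted p = 0.130). Both were lost with the barcode minimum as a term (means 0.0682 and 0.0636), where TFF1 reversed to -0.0954.

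Cell cycle genes were higher as a set in CD goblet cells (21 of 26 positive, mean log2 fold 0.56, adjusted p = 3.52e-06, and adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone, 8 rose and 18 did not pass. Examples were RRM2 (1.30 ± 0.24, adjusted p = 0.243), BIRC5 (1.23 ± 0.28), AURKB (1.23 ± 0.34) and CCNB1 (0.91 ± 0.25). The call was lost and the mean reversed to -0.05 with at most 25% mitochondrial UMIs (adjusted p = 0.226). Metallothionein genes were lower as a set (14 of 18 negative, mean log2 fold -0.23, adjusted p = 0.0476, and adjusted p = 0.611 with an estimated correlation), where 1 fell adjusted over the list alone. Examples were MT1X (-0.65 ± 0.16), MT1G (-0.57 ± 0.23), MT1M (-0.66 ± 0.29) and MT1H (-0.66 ± 0.34). This call was lost without CD replicate 2 (adjusted p = 0.106), CD replicate 3 (0.248), nIBD replicate 2 (0.0564) or nIBD replicate 4 (0.144), and with at most 25% mitochondrial UMIs (0.271).

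Camera called 2 lists of other cell types in goblet cells, with no member past the test over all genes or over the list alone. Plasma cell genes (4 positive and 3 negative folds, mean log2 fold 0.74, adjusted p = 0.0436, and adjusted p = 0.705 with an estimated correlation) included IGLC3 (3.03 ± 1.31), IGHM (1.81 ± 1.08), IGLC2 (1.15 ± 0.75) and DERL3 (0.64 ± 0.50). IGLC3 was at 0.33 without CD replicate 1, 3.62 without CD replicate 3 and 4.03 without nIBD replicate 1, and IGLC2 at 1.79 without nIBD replicate 2. The plasma call was lost without CD replicate 1 (adjusted p = 0.120), CD replicate 2 (0.132), nIBD replicate 1 (0.0900), nIBD replicate 3 (0.0551) or nIBD replicate 4 (0.539). It was also lost without doublet removal (0.191, mean -0.21), with at most 25% mitochondrial UMIs (0.145), without integration (0.0751) and at Leiden resolution 2.0 (0.0823). T and NK genes (3 measured, all positive, mean log2 fold 1.01, adjusted p = 0.0459, and adjusted p = 0.616 with an estimated correlation) were PTPRC (1.44 ± 0.70), CCL5 (1.0 ± 0.52) and CD7 (0.58 ± 0.59). Their mean was 0.28 without CD replicate 2 and reversed to -0.16 when doublets were kept and to -0.63 without both libraries of high minimum, and CD7 was at 1.37 without nIBD replicate 4. The T and NK call was lost without CD replicate 2 (adjusted p = 0.428), CD replicate 3 (0.281), nIBD replicate 2 (0.102) or nIBD replicate 3 (0.14). It was also lost without doublet removal (0.894), with at least 1000 genes per cell (0.116) and without low-UMI clusters (0.0520).

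Camera called none of the remaining lists in goblet cells. The stem cell and Wnt list had mean log2 fold -0.22, adjusted p = 0.0537, ion and water transport -0.09, adjusted p = 0.120, nuclear oxidative phosphorylation -0.07, adjusted p = 0.110 and ribosomal proteins -0.05, adjusted p = 0.116. Interferon gamma response had 0.11, adjusted p = 0.230, mitochondrial-encoded genes 0.05, adjusted p = 0.817, fatty acid oxidation -0.08, adjusted p = 0.206, butyrate handling -0.07, adjusted p = 0.821 and hypoxia -0.02, adjusted p = 0.652. Cholesterol synthesis had -0.02, adjusted p = 0.850, dissociation genes 0.03, adjusted p = 0.861, tight junctions 0.08, adjusted p = 0.446, CD susceptibility genes 0.11, adjusted p = 0.821 and xenobiotic targets -0.09, adjusted p = 0.574. Ileal genes had -0.01, adjusted p = 0.326 (median 0.13) and stromal genes 0.33, adjusted p = 0.306, and distal colon and myeloid genes had under 3 members measured. The test leaned against the sign of the mean for dissociation, cholesterol and ileal genes.

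In undifferentiated cells, the stem, progenitor and cycling cells of the crypt, HLA-DRB1, IFITM1 and CCL28 were higher in CD without passing edgeR's test over 14382 genes. CCL28, a mucosal chemokine that draws antibody-secreting cells, stood at 36.2 ± 7.75 CPM in CD and 17.4 ± 1.48 CPM in nIBD (chromosome 5, 43376645 to 43412391, log2 fold 1.06 ± 0.15, adjusted p = 0.242, DESeq2 adjusted p = 7.39e-06, 3 CD and 4 nIBD samples). IFITM1 (log2 fold 2.51 ± 0.33, adjusted p = 0.155) had DESeq2 adjusted p = 2.79e-09. HLA-DRB1 stood at 116 ± 9.33 CPM in CD and 8.93 ± 4.62 CPM in nIBD (log2 fold 3.69 ± 0.44, adjusted p = 0.117). At unadjusted p below 0.05 edgeR listed 1605 genes (816 higher and 789 lower, 719 by chance). DESeq2 called 170 genes (94 higher and 76 lower), and 12% of genes did not overlap, against 5.71% by chance. Without CD replicate 1 edgeR called 28 genes.

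Other undifferentiated genes of small p, each at adjusted p = 0.266, were the differentiation inhibitor ID1, at 644 ± 44.0 CPM in CD and 352 ± 50.7 CPM in nIBD (log2 fold 0.87 ± 0.14), the mitochondrial enzyme FAHD1 (0.71 ± 0.11), the nitric oxide synthase adaptor NOS1AP (0.82 ± 0.15) and DUOX2 (log2 fold 3.49 ± 0.64, 2.45 without CD replicate 3). WASHC1 (1.06 ± 0.17), of a family with near copies, CXorf40B (1.14 ± 0.21), which also has a near copy, and the pseudogene HNRNPA1P48 (-1.76 ± 0.30) are less certain because reads may be shared.

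Antigen presentation was higher as a set in CD undifferentiated cells. All 8 measured MHC class II members were positive (mean log2 fold 1.5, adjusted p = 8.37e-06, and adjusted p = 0.587 with an estimated correlation). Of its members 1 rose adjusted over the list alone, and 7 did not pass. HLA-DRA (1.94 ± 0.78), HLA-DPB1 (1.58 ± 0.77) and HLA-DMA (1.13 ± 0.61) came after HLA-DRB1. The list mean was 2.42 without 1 nIBD library, where HLA-DRA was at 2.81 and HLA-DMA at 2.0, and HLA-DPB1 was at 0.92 without CD replicate 3. MHC class I genes (16 of 16 positive, mean log2 fold 0.43, adjusted p = 7.71e-05, and adjusted p = 0.711 with an estimated correlation) included HLA-C (1.0 ± 0.21), HLA-E (0.56 ± 0.22), PSMB8 (0.56 ± 0.30) and the peptide loader TAPBP (0.33 ± 0.18). Adjusted over the list alone 1 rose, and the call was lost without CD replicate 3 (adjusted p = 0.0758). Type I interferon genes (12 of 20 positive, mean log2 fold 0.28, adjusted p = 0.0476, and adjusted p = 0.830 with an estimated correlation) included IFITM1, the only member that rose adjusted over the list alone, ISG20 (0.65 ± 0.18), ISG15 (0.79 ± 0.37) and OASL (0.56 ± 0.34). That interferon call was lost without CD replicate 1 (adjusted p = 0.0681), CD replicate 3 (0.281), nIBD replicate 1 (0.0702), nIBD replicate 2 (0.101) or nIBD replicate 3 (0.449). It was also lost at Leiden resolution 2.0 (0.0677), with DESeq2 size factors (0.0544), without the low-count filter (0.255), without low-UMI clusters (0.0608) and in stem or progenitor cells alone (0.177). Without both libraries of high minimum its mean was -0.29 and ISG15 was at -0.17.

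Defence genes were higher as a set in CD undifferentiated cells (12 of 19 positive, mean log2 fold 0.87, adjusted p = 0.00185, and adjusted p = 0.587 with an estimated correlation). 6 members rose adjusted over the list alone, and 13 did not pass. LCN2 stood at 519.6 ± 289 CPM in CD and 104 ± 39.7 CPM in nIBD (log2 fold 2.32 ± 0.43, adjusted p = 0.266, and 2.63 ± 0.24, adjusted p = 0.000596 in stem or progenitor cells alone), with DUOX2, the elastase inhibitor PI3 (2.32 ± 0.58) and S100P (2.46 ± 0.63). PI3 was at 1.12 without CD replicate 3 and S100P at 1.21 without CD replicate 2. NF-kB targets had 16 positive folds of 18 (mean log2 fold 0.51, adjusted p = 0.000935, and adjusted p = 0.587 with an estimated correlation), and 1 rose adjusted over the list alone. CCL28, CCL20 (1.51 ± 0.53), complement factor CFB (0.74 ± 0.33) and the survival factor BIRC3 (0.57 ± 0.30) were the examples, with CCL20 at 0.67 without CD replicate 3.

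Mucus genes were higher as a set in CD undifferentiated cells (19 of 23 positive, mean log2 fold 0.36, adjusted p = 0.000310, and adjusted p = 0.587 with an estimated correlation). The class includes a cycling cluster led by as many goblet as cycling markers, 12.3 ± 1.95% of its cells in CD and 12.9 ± 2.72% in nIBD (exact permutation p = 0.80), and without that cluster the list was still called (mean 0.48, adjusted p = 0.00124). Adjusted over the list alone, 5 rose and 18 did not pass. The gel mucin MUC2 stood at 186 ± 45.7 CPM in CD and 102 ± 25.1 CPM in nIBD (log2 fold 0.86 ± 0.22), with TFF1 (1.82 ± 0.36), B3GNT6 (1.39 ± 0.32) and MUC4 (0.55 ± 0.11). Unfolded protein response genes (23 of 26 positive, mean log2 fold 0.25, adjusted p = 0.000303, and adjusted p = 0.611 with an estimated correlation) included SDF2L1 (0.86 ± 0.17), HSPA5 (0.72 ± 0.25), DNAJB11 (0.55 ± 0.21) and CALR (0.27 ± 0.12), and 1 rose adjusted over the list alone. That mean reversed to -0.0410 with the barcode minimum as a term.

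Stem cell and Wnt genes were lower as a set in CD undifferentiated cells, the opposite direction to absorptive colonocytes (14 of 18 negative, mean log2 fold -0.46, adjusted p = 0.000307, and adjusted p = 0.587 with an estimated correlation). Of its members 1 fell adjusted over the list alone, and 17 did not pass. The MYC target CDCA7 stood at 45.7 ± 12.4 CPM in CD and 82.7 ± 9.48 CPM in nIBD (log2 fold -0.85 ± 0.19), with MYC (-0.69 ± 0.22), the BMP co-receptor RGMB (-0.94 ± 0.30) and the Wnt inhibitor ZNRF3 (-0.68 ± 0.23), CDCA7 and RGMB being also markers of the class. Cycling cells were 89.6 ± 5.76% of the class in CD and 85.2 ± 4.07% in nIBD (exact permutation p = 0.257). In stem or progenitor cells alone the list was again called lower (mean -0.56, adjusted p = 2.91e-06). List members such as RGMB also named those cells, so this is no separate check. Ribosomal protein genes were lower by a small mean (33 of 49 negative, mean log2 fold -0.11, adjusted p = 0.00705, and adjusted p = 0.853 with an estimated correlation), with RPS25 (-0.44 ± 0.15), RPS13 (-0.39 ± 0.15), RPL27 (-0.37 ± 0.13) and RPL4 (-0.36 ± 0.12) and none past the test adjusted over the list alone. With the barcode minimum as a term the ribosomal mean reversed to 0.21. The ribosomal call was lost without CD replicate 2 (adjusted p = 0.411), CD replicate 3 (0.530), nIBD replicate 3 (0.0550) or nIBD replicate 4 (0.191).

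Lists that camera did not call in undifferentiated cells began with genes of other cell types, namely plasma cells (mean log2 fold 1.96, adjusted p = 0.0681), T and NK cells (0.51, adjusted p = 0.0859) and stromal cells (0.16, adjusted p = 0.374). Metallothioneins had -0.23, adjusted p = 0.0703, hypoxia 0.11, adjusted p = 0.0921, tight junctions 0.17, adjusted p = 0.108, CD susceptibility genes 0.16, adjusted p = 0.230 and the cell cycle -0.07, adjusted p = 0.320. Interferon gamma response had -0.10, adjusted p = 0.454, mitochondrial-encoded genes 0.10, adjusted p = 0.300, nuclear oxidative phosphorylation -0.02, adjusted p = 0.907, fatty acid oxidation -0.0047, adjusted p = 0.955 and butyrate handling 0.10, adjusted p = 0.651. Ion and water transport had 0.17, adjusted p = 0.513, dissociation genes 0.12, adjusted p = 0.955, cholesterol synthesis -0.07, adjusted p = 0.670, xenobiotic targets 0.05, adjusted p = 0.681, ileal genes -0.25, adjusted p = 0.306 and distal colon genes 0.35, adjusted p = 0.976. Myeloid genes had under 3 members measured, and the test leaned against the sign of the mean for interferon gamma, nuclear oxidative phosphorylation, cholesterol and ileal genes. The median was 0.02 for interferon gamma, -0.17 for distal colon and -0.01 for stromal genes.

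**Figure D3:**
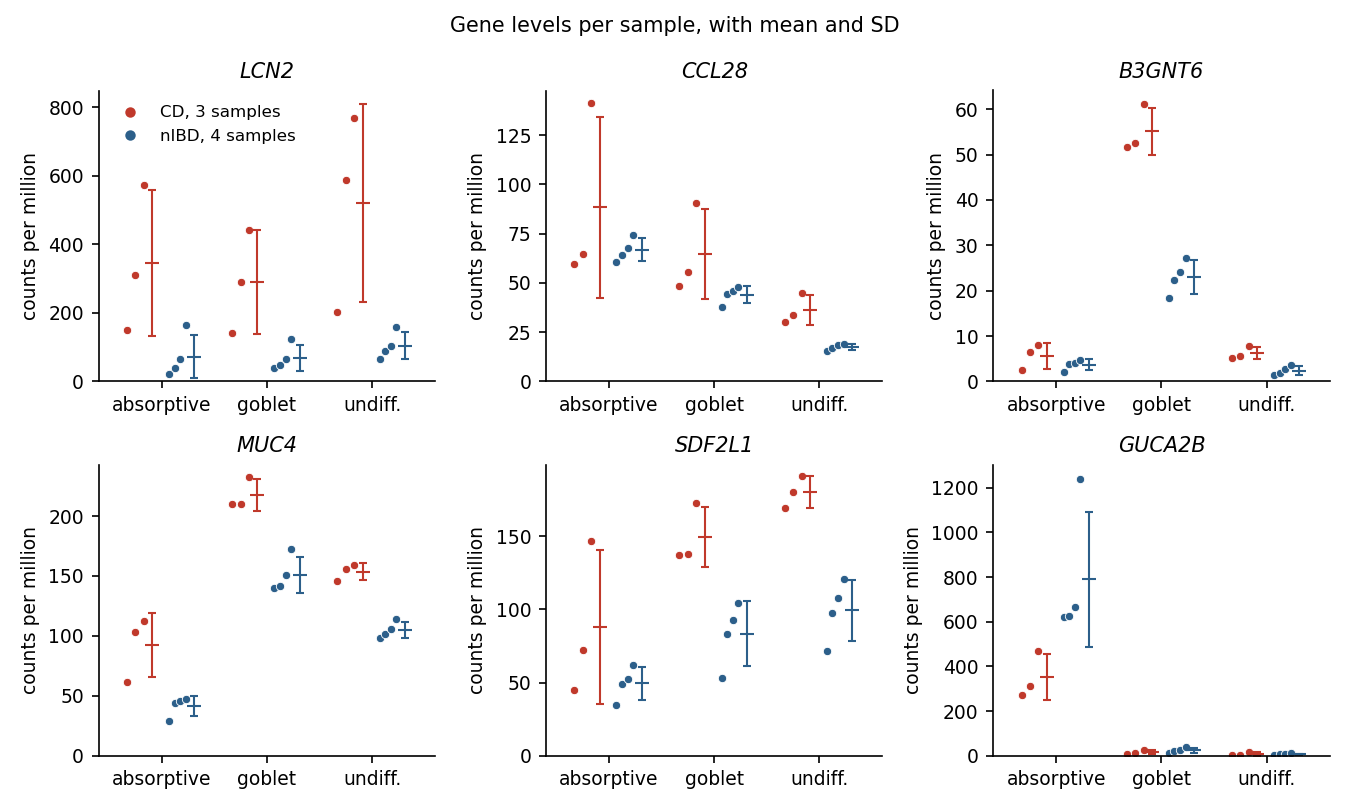
CPM (vertical axes) of LCN2, CCL28, B3GNT6, MUC4, SDF2L1 and GUCA2B in absorptive colonocytes, goblet cells and undifferentiated cells, 1 point per sample, with the mean and SD of each group to the right of its points. In goblet cells B3GNT6 averaged 55.1 CPM in CD and 23.0 CPM in nIBD, with no overlap.

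BEST4+ cells gave 2 calls among 9700 genes, both higher in CD. HLA-DRB1 rose, at 101 ± 29.6 CPM in CD and 5.90 ± 5.70 CPM in nIBD (log2 fold 4.21 ± 0.51, edgeR adjusted p = 0.0101, 3 CD and 4 nIBD samples). NPR1, the receptor for atrial natriuretic peptide, had 28 UMIs over the CD libraries and 0 over the nIBD libraries (adjusted p = 0.0282). It was at least 26.3-fold higher against a floor of 3 counts over the nIBD group, and it was named after its values were seen. HLA-DRB1 lost its call without CD replicate 1 (log2 fold 4.22, adjusted p = 0.0521) and was at 5.26 without 1 nIBD library. Both calls ended with the barcode minimum as a term and without both libraries of high minimum, fits that rest on a single CD library of low minimum, with HLA-DRB1 at 4.21 ± 0.67 and 4.20 ± 0.69. The count of calls ran from 0 to 6 with 1 sample left out. At unadjusted p below 0.05 edgeR listed 800 genes (412 higher and 388 lower, 485 by chance), and DESeq2 called 19 genes.

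Over all epithelial cells edgeR called no gene among 17348, listed 1654 at unadjusted p below 0.05 (867 by chance), and DESeq2 called 225. The smallest p-values belonged to HLA-DRB1 (4.16 ± 0.43, adjusted p = 0.101), IFITM1 (2.58 ± 0.36, adjusted p = 0.226), FAHD1 (0.79 ± 0.11) and XDH, the purine enzyme that makes uric acid, at 37.0 ± 2.20 CPM in CD and 22.6 ± 1.37 CPM in nIBD (log2 fold 0.71 ± 0.10, adjusted p = 0.226, 3 CD and 4 nIBD samples). Higher values also came from the hair-cell protein LHFPL5 (2.03 ± 0.33), from EID3 (1.64 ± 0.28) and from the proton pump subunit TCIRG1 (0.81 ± 0.14). Lower values came from INSM1 (-1.96 ± 0.34), a transcription factor of enteroendocrine cells, from HNRNPA1P48 (-1.66 ± 0.29) and from TRIM52-AS1 (-0.99 ± 0.17).

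No gene was called by edgeR as differing in its disease effect between classes. Goblet cells against absorptive colonocytes gave 0 calls of 14223 genes in edgeR (1336 at unadjusted p below 0.05, 711 by chance, DESeq2 11), and undifferentiated cells against absorptive colonocytes gave 0 of 14946 (1792, 747 by chance, DESeq2 106). Without CD replicate 1 the counts were 49 and 165, and the first was 1 without CD replicate 3 and 2 without nIBD replicate 4.

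With the barcode minimum as a term in the model, 4 of the 32 lists were still called, 3 of them in the same direction. These were ion and water transport (mean log2 fold -0.67) and unfolded protein response (0.34) in absorptive colonocytes, the cell cycle in goblet cells (0.31), and ribosomal proteins in undifferentiated cells with the sign reversed (0.21). The MHC class II means were 0.88 in absorptive colonocytes, 1.20 in goblet cells and 1.04 in undifferentiated cells. The conflicting library counted as CD also ended the absorptive calls of ion and water transport (adjusted p = 0.157), mucus (0.22) and plasma cell genes (0.0941), and the T and NK call of goblet cells (0.0738). In undifferentiated cells it ended those of type I interferon (0.185), NF-kB (0.0912), mucus (0.0551) and unfolded protein response (0.0842). Among the libraries of low minimum only 1 CD library stands against 4 nIBD libraries, and those of high minimum are CD alone.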

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

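The list contrasts between classes and the T or NK comparison were added after the comparisons were fixed and before their results were seen, while the fits with the barcode minimum as a term and without both libraries of high minimum were chosen after results had been seen.

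The disease effect differed between absorptive colonocytes and goblet cells for 8 gene lists, by camera on the interaction with the preset correlation. With an estimated correlation none of these passed (adjusted p = 0.410 or more). The effect was lower in goblet cells for MHC class II (adjusted p = 0.0145), cholesterol synthesis (1.81e-09), the cell cycle (0.0104), stem cell and Wnt targets (9.92e-09) and ribosomal proteins (0.00116). It was higher there for MHC class I (5.78e-06), mitochondrial-encoded genes (0.00073) and T and NK genes (4.68e-05). OLFM4 of the stem cell list was among the genes behind the absorptive side, but reversed with the barcode minimum as a term.

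Undifferentiated cells differed from absorptive colonocytes in 10 lists with the preset correlation and in none with an estimated one (adjusted p = 0.410 or more). The disease effect was lower in undifferentiated cells for MHC class II (adjusted p = 0.0325), cholesterol synthesis (4.77e-07), the cell cycle (9.61e-14), stem cell and Wnt targets (3.50e-09) and ribosomal proteins (0.000389). It was higher for MHC class I (7.74e-05), mitochondrial-encoded genes (5.70e-05), nuclear oxidative phosphorylation (0.000575), ion and water transport (2.56e-05) and T and NK genes (0.00779). Stem cell and Wnt genes had opposite mean log2 folds, 0.81 in absorptive colonocytes and -0.46 in undifferentiated cells. The opposite direction was gone with the barcode minimum as a term (absorptive mean -0.54), without both libraries of high minimum (-0.65) and with at most 25% mitochondrial UMIs (-0.0027). For single genes edgeR made no call in either contrast.

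Samples far from the rest of their group turned up in 10 of 197 groups tested, where chance gives about 1 in 20, or 9.85. Only nIBD was tested, by the gap beside the outermost sample over the range of the 4 samples. This ratio was 0.944 for the share of B cells, 0.851 for that of the unnamed epithelial cluster led by CFTR and ADH1C and 0.848 for the median UMI count of all barcodes. In absorptive colonocytes it was 0.900 for GUCA2B, 0.872 for CA4, 0.842 for MUC4 and 0.943 for the mean level of the stem cell and Wnt list. In undifferentiated cells it was 0.830 for ISG20, 0.859 for ISG15 and 0.844 for MYC.

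Barcodes with more than 50% mitochondrial UMIs, which no comparison of genes used, made up 60.5% of CD barcodes on average against 36.7% in nIBD (exact permutation p = 0.0286). T or NK cells, outside the epithelium, gave 22 calls in edgeR, 18 higher and 4 lower in CD.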

How the results depend on the processing

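The barcode minimum as a term, leaving out both libraries of high minimum, leaving out clusters of few UMIs, leaving out the cycling cluster with goblet markers, and stem or progenitor or crypt-top cells alone were chosen after results had been seen, the T or NK comparison was added before its own, and the other settings were planned. In the fits without both libraries a lone CD sample is assumed to vary like the nIBD group. The cause of the changes was not tested. No paired analysis was possible because the labels give no number or pairing that joins a CD to an nIBD sample. Alternatives not run were those of tuft and enteroendocrine cells, and BEST4+ cells with at most 25% mitochondrial UMIs, for want of cells. No class share was called under any setting, which the exact test could not do for a single class, and the edgeR test of cell counts had adjusted p of 0.722 or more.

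Gene calls depended on the tool and the samples. In absorptive colonocytes the 1 call became 0 with at most 25% mitochondrial UMIs, with the conflicting library as CD and without both libraries of high minimum, 3 with the barcode term, 76 without the low-count filter and 101 with DESeq2 (1 with each sample left out). In goblet cells 0 became 2 with at most 25% mitochondrial UMIs, 31 without the filter, 41 with the term, 1 without both libraries and 96 with DESeq2 (0 to 1 with 1 sample left out). In undifferentiated cells 0 became 1 with at most 25% mitochondrial UMIs, 9 without the filter, 3 without both libraries, 2 in stem or progenitor cells alone and 170 with DESeq2 (0 to 28). In BEST4+ cells 2 became 1 without doublet removal, 22 with the conflicting library as CD, 180 without the filter, 0 with the term, 0 without both libraries and 19 with DESeq2 (0 to 6). In all epithelial cells 0 became 2 without the filter, 1 without both libraries and 225 with DESeq2 (0 to 2).

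For the interaction with goblet cells 0 became 181 without the filter, 1 with the term, 1 without both libraries and 11 with DESeq2 (0 to 49). For that with undifferentiated cells 0 became 3 with at most 25% mitochondrial UMIs, 2 with at least 1000 genes, 525 without the filter, 2 with the term, 2 without both libraries and 106 with DESeq2 (0 to 165). The 32 list calls became 7 with the term, 8 without both libraries and 0 with an estimated correlation or fry (25 to 37 with 1 sample left out). In T or NK cells 22 became 2 with at most 25% mitochondrial UMIs, 3 with at least 1000 genes, 9 without doublet removal, 1 without integration, 0 with the conflicting library as CD, 711 without the filter, 15 with the term, 13 without both libraries and 221 with DESeq2 (0 to 1324).

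Some log2 folds changed sign. With at most 25% mitochondrial UMIs these were, in absorptive colonocytes, CD44 (-0.12), FTH1 (0.16) and IGHM (-2.71), and in goblet cells IGLC3 (-0.77). Without CD replicate 2 absorptive IGKC was at -0.0048, and at 2.76 without nIBD replicate 2. Without doublet removal goblet IGLC3 was at -1.82, CCL5 at -0.51 and CD7 at -0.17. With the barcode term, then without both libraries of high minimum, absorptive values were DUOXA2 -0.66 and -0.66, CXCL1 -0.83 and -0.83, CXCL3 -0.37 and -0.36, CXCL8 -2.80 and -2.80, MUC5B -0.0301 and -0.0229, GALNT5 -0.39 and -0.39, STARD4 -0.42 and -0.41, OLFM4 -0.98 and -0.98, and LEFTY1 -0.33 and -0.33. Goblet values were CCL20 -0.0896 and -0.0783 and TFF1 -0.0954 and -0.0858, and undifferentiated ISG15 was at -0.17 in both.

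List means changed sign too. With at most 25% mitochondrial UMIs the stem cell and Wnt mean in absorptive colonocytes was -0.0027 and the cell cycle mean in goblet cells -0.0459. The T and NK mean in goblet cells was -0.16 without doublet removal, and the absorptive cholesterol mean -0.0777 with the conflicting library as CD. Plasma means were, in absorptive colonocytes, -0.736 with at most 25% mitochondrial UMIs, -0.110 without integration and -0.355 without CD replicate 2, and in goblet cells -0.207 without doublet removal. With the term, then without both libraries, absorptive means were defence -0.33 and -0.33, plasma -0.0817 and -0.146, NF-kB -0.19 and -0.29, mucus -0.48 and -0.48, cholesterol -0.19 and -0.18, cell cycle -0.33 and -0.32, and stem cell and Wnt -0.54 and -0.65, while undifferentiated means were unfolded protein response -0.0410 and -0.0393 and ribosomal proteins 0.21 and 0.21. Differences of logit shares changed sign for cycling cells (-0.0063 with at most 25% mitochondrial UMIs, -0.0075 without CD replicate 3, -0.101 without nIBD replicate 3), for crypt-top colonocytes (0.344, then 0.0620 without CD replicate 1, 0.0351 without CD replicate 3 and 0.0555 without nIBD replicate 3, lowest -0.218 without CD replicate 2), for T or NK cells (-0.118, -0.122 with at least 1000 genes and -0.197 without nIBD replicate 3, highest 0.295 without nIBD replicate 4) and for early colonocytes (-0.730 without integration).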

Other observations

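The tests of the MHC class II list without HLA-DRB1, of that list with the barcode minimum as a term of LCN2 with that term and of the share of the unnamed cluster with T or NK and cycling markers were chosen after the results were seen, as was the barcode term itself, while the T or NK comparison was added after the comparisons were fixed and before its result was seen.

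Of the 22 genes called in T or NK cells, some belong to dividing cells and some to epithelium, a grouping made by eye. In CD, MKI67 (log2 fold 2.78 ± 0.35, edgeR adjusted p = 0.0104), ASPM (3.74 ± 0.47), BIRC5 (3.07 ± 0.40), TOP2A (2.61 ± 0.40), PCLAF (2.78 ± 0.45), NUSAP1 (1.79 ± 0.31), TYMS (1.93 ± 0.34) and STMN1 (1.76 ± 0.27), all genes of dividing cells, rose among 9066 genes, in 3 CD against 4 nIBD samples. Genes that epithelium expresses rose beside them, among them LCN2 (3.72 ± 0.57), PDGFA (2.22 ± 0.36), DSC2 (2.10 ± 0.37), SOX4 (1.92 ± 0.35), PHLDA2 (1.89 ± 0.28), DSP (1.85 ± 0.32), EMP1 (1.85 ± 0.28), RND3 (1.69 ± 0.30) and PRSS3 (1.40 ± 0.25). CLECL1, a lectin-like gene of lymphocytes, fell to 5.39 ± 4.18 CPM from 66.9 ± 15.9 CPM (log2 fold -3.81 ± 0.43, adjusted p = 0.00921), and CITED2 (-1.44 ± 0.24), a transcriptional co-regulator, OTUD6B-AS1 (-1.19 ± 0.20), an antisense transcript, and RPS10 (-1.64 ± 0.29), which overlaps a readthrough transcript, also fell.

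Epithelial RNA made up 25.9 ± 15.1% of the RNA in T or NK cells in CD and 8.39 ± 0.396% in nIBD. The share of the T or NK difference that this predicts was 143% for LCN2, 126% for PHLDA2, 121% for DSP, 104% for PRSS3, 102% for EMP1, 93.0% for DSC2, 78.3% for RND3, 73.0% for PDGFA and 69.0% for SOX4. It was 66.8% for TOP2A, 53.6% for ASPM, 43.9% for MKI67, 42.5% for NUSAP1, 40.5% for BIRC5, 17.4% for PCLAF, 13.7% for TYMS and 12.8% for STMN1. The count of 22 calls was 1324 without CD replicate 1, 7 without CD replicate 2, 0 without CD replicate 3, 0 without nIBD replicate 1, 9 without nIBD replicate 2, 4 without nIBD replicate 3 and 0 without nIBD replicate 4. DESeq2 called 221 genes, and edgeR listed 1364 at unadjusted p below 0.05 (453 by chance).

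The higher genes of CD T or NK cells are one pattern to weigh. Epithelial RNA or cells among them predicted a median of 71.0% of the difference over the 18 genes (56.5% to 94.9% with 1 sample left out), and at least 50% for 12 of the 18. Mixing with epithelium may therefore account for most of the epithelial genes, while it predicted little of STMN1, TYMS and PCLAF. Whether T cells divide more in CD stays open. An unnamed cluster of 75 cells with T or NK and cycling markers lay outside the class and made up 0.341 ± 0.327% of kept cells in CD and 0.0801 ± 0.0474% in nIBD (exact permutation p = 0.371). Of the 35 splits 2 gave as many calls, the real one and another with 140, so chance cannot be excluded.

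The higher MHC class II genes in CD are the second pattern. B or myeloid RNA argues poorly for it, since the markers of both types predicted 7.56%, 24.8% and -0.323% of the HLA-DRA difference in absorptive, goblet and undifferentiated cells (up to 16.9%, 35.5% and 1.44% with 1 sample left out), with B markers at 1.93 CPM in CD absorptive colonocytes and 3370 CPM in B cells. Reads of HLA-DRB1 shared with other DRB genes stay open as a cause, though all 8 members were positive in each class. Without HLA-DRB1 the list was called in 3 of 3 classes at the preset correlation of 0.01 (adjusted p = 9.77e-06, 0.000125 and 0.000444). The whole list had estimated correlations of 0.57 to 0.84, so that test cannot decide. With those it was called in no class (adjusted p = 0.587 in each), and without HLA-DRB1 it was not tested. The barcode minimum cannot be told apart from disease here: with it as a term 0 of 3 classes were called, with mean log2 folds of 0.88, 1.20 and 1.04 (2.08, 1.54 and 1.5 without it) that rest on a single CD library of low minimum. Response of epithelium to cytokines in CD could apply and was not tested, and interferon gamma genes had mean log2 folds of 0.49, 0.11 and -0.10 that did not pass.

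Higher LCN2 in CD epithelium is the third pattern. Free RNA does not account for it, because the LCN2 difference per cell was 14.8, 15.1 and 38.8 times that in T or NK cells in absorptive, goblet and undifferentiated cells, with 4.33 ± 3.39, 5.11 ± 2.76 and 11.6 ± 6.42 UMIs per cell in CD, 0.917 ± 0.801, 1.63 ± 0.670 and 2.69 ± 0.83 in nIBD, and 0.246 ± 0.178 and 0.0155 ± 0.0151 in T or NK cells. The barcode minimum cannot be told apart from disease here either. LCN2 was called in 0 of 3 classes with it as a term, as without it. The log2 folds with the term were 2.11 ± 0.90, 2.68 ± 0.51 and 2.88 ± 0.50, against 2.25 ± 0.65, 2.08 ± 0.44 and 2.32 ± 0.43 without it. The term did not remove the difference, but its folds rest on a single CD library of low minimum. A defence response of the epithelium in CD could also apply and was not tested. LCN2 passed edgeR's test in stem or progenitor cells alone (2.63 ± 0.24, adjusted p = 0.000596), a setting chosen after results had been seen, and not in absorptive, goblet or undifferentiated cells (adjusted p = 0.40, 0.243 and 0.266), and depth, which was lower in CD, was not tested as a cause.

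All 35 splits of the samples were run through the same tests. Chance among 7 samples taken as alike can be excluded for the genes at unadjusted p below 0.05 in goblet cells (1261, highest other 1009), undifferentiated cells (1605, highest other 1204) and all epithelial cells (1654, highest other 1423), where only 1 of 35 splits, the real one, reached the count. This does not separate disease from the barcode minimum. Both libraries of high minimum stay in the group of 3 in only 4 other splits, whose counts were 635 to 931, 886 to 1204 and 955 to 1274, and among so few the real split cannot reach p below 0.05. Nor can chance be excluded for the genes at unadjusted p below 0.05 in absorptive colonocytes (1181, reached by 3 splits, highest other 1307). The same holds for the calls in absorptive colonocytes (1, reached by 4, highest other 2) and BEST4+ cells (2, reached by 6, highest other 22). The 32 list calls were reached by 12 of the 35 splits (highest other 41, with both libraries of high minimum together). Chance cannot be excluded for their number, and was not tested for single lists. Counts of 0 calls are reached by all 35 splits, in goblet cells (highest other 5), undifferentiated cells (6), all epithelial cells (2) and the interactions with goblet (6) and undifferentiated cells (5).

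Clusters without a name held much of the epithelium. The largest, led by CFTR and ADH1C, had 7263 cells and 22.1 ± 1.17% of epithelial cells in CD against 19.7 ± 2.24% in nIBD (exact permutation p = 0.171). A cluster of 1639 cells had a median of 1589 UMIs, a small part of a sample's usual depth. A cluster of 158 cells carried mast and tuft genes together and made up 0.586 ± 0.554% in CD and 0.276 ± 0.132% in nIBD (exact permutation p = 0.429). Cycling shares of undifferentiated cells, given above, overlapped between the groups.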
